A study of Mus musculus with 7 samples.

How the data were processed

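Liver RNA from 7 mice was profiled on 2-colour arrays, 4 wild type (1 female and 3 males) and 3 carrying a Zfp90 transgene (1 female and 2 males). Per the labels, each animal's Cy5-labelled RNA was set against a Cy3-labelled pool of liver RNA from 4 wild-type mice of both sexes, RNA was purified on spin columns with DNase, and dye swaps were used. The deposited table holds 1 log10 ratio per probe and animal for 23574 probes. How the swapped hybridisations were combined, and which background correction and normalization the authors used, is not given in the sources used here, and scanner intensities were not used here. Signal over background is therefore unknown for every probe, and the number of arrays limits the precision.

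Direction, log base and centring of the deposited ratios are unstated in the labels and were settled from the values. The values end at exactly -2 and 2, the range of a log10 scale limited at 100-fold. The Y-linked gene Kdm5d lay far below 0 on both female arrays (-3.22 and -2.54 after conversion to log2) and above 0 on all 5 male arrays (0.14 to 0.66), so positive values were read as animal over pool on each array. If 1 of the 4 pooled mice was female, a transcript absent from males has a ratio of 0.602 on the log10 scale in a female. The 7 probes under -0.9 on all 5 male arrays had median log10 values of 0.548 on the array labelled wild-type female and 0.608 in the transgenic female. The column medians ran from -0.0042 to 0.0093 on the log10 scale, and how the columns were centred stays unknown. Correlations between arrays over all probes were below -0.3 for 3 pairs: wild-type male 4 with the transgenic female (-0.497), and the array labelled wild-type female with wild-type male 3 (-0.363) and wild-type male 2 (-0.307). The highest correlation was 0.526, between wild-type males 2 and 4. The direction was kept because Kdm5d settled it array by array. That the pooled mice were the 4 wild-type animals on the arrays is not stated in the labels. With every sign turned, each difference below would change its sign and keep its p.

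Ratios were multiplied by 3.32 to give log2 ratios. GEO's platform annotation paired 17824 probes with 1 gene symbol and 50 with several, and 5700 had none there. Symbols were looked up by gene number in NCBI's gene table for assembly GRCm38.p6, and 0 needed an update. Probes of 1 gene were averaged (1150 genes had more than 1 probe), and probes without a single symbol were kept on their own, giving 22218 features, of which 16468 were named genes. There were 0 missing values. Named probes included the Y-linked genes Kdm5d and Uty, while Xist, Ddx3y and Eif2s3y had none.

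Differences were fitted with limma (version 3.58.1, R 4.3.3), lmFit and eBayes, in a model with genotype and sex over all 7 arrays. The interaction of genotype and sex was fitted in a model of its own, with 1 female per genotype, so its spread came from the males. P-values were adjusted by Benjamini-Hochberg over all features and called at 0.05. Group values are means with the SD over animals, and model differences are given with their standard error (SE). A set of 36 gene lists for liver metabolism, sex-biased expression, stress, immunity, cell types and the genes beside Zfp90 was tested with limma's camera on named genes at an inter-gene correlation of 0.01, adjusted over the lists. Camera with a correlation estimated for each list, and fry, were run beside it. The proteasome list had a negative median (-0.015) beside a positive mean (0.004) and an upward test, and the neutrophil list a negative median and mean (-0.004 and -0.008) beside an upward test. Of Zfp90 itself, the group means were also compared by an exact permutation test over the 35 splits of the animals into 3 and 4. Other splits of the samples were fitted with the same model.

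The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Zfp90, the genes past the threshold with no overlap between genotypes or, with fewer than 5 past it in a direction, the 8 named genes with the smallest p in each direction, and up to 4 members with the smallest p from each list. For the sexes it named the Y-linked genes and the 5 largest differences each way past the threshold, and for the interaction the 5 named genes with the smallest adjusted p. Alternatives were centring each array on its median, quantile normalization between arrays, leaving out the sex or genotype term, males alone, a robust variance model, array weights, single probes, named genes alone, the 50% of features with the largest mean ratio in size, and leaving out each animal.

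The fit was tested on simulated data with 22218 features for the comparison of transgenic with wild type. It recovered 39 of 100 features changed 1.5-fold and 98 of 100 changed 3-fold, with 6 false calls among 143. The simulated noise was independent between features and alike on all arrays, and the planted changes ease the adjusted threshold. In the real data Scd1 (3.02-fold) and Cd36 (3.04-fold) did not pass, so these counts do not exclude missed changes of that size. Camera recovered 20 of 20 simulated lists of 20 genes shifted by 0.3 and called 0 of 80 unshifted lists, at either correlation, with genes simulated as independent.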

Results

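Liver expression was measured in 7 mice, each against the same pool of wild-type liver RNA. The wild-type group held 4 animals (1 female, 3 males) and the group carrying a transgene for the zinc finger protein Zfp90 held 3 (1 female, 2 males). The design asks which liver transcripts differ in the transgenic animals, and the labels also give each animal's sex. All values are log2 ratios to the pool unless a fold is given, for 22218 features on 7 arrays with medians between -0.01 and 0.03.

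Zfp90, the gene carried by the transgene, was 1.40-fold higher in the transgenic animals in the model with sex (difference 0.48 ± 0.15 SE). Its ratios were 0.58 and 0.45 in the transgenic males, against -0.15, -0.29 and -0.11 in the 3 wild-type males, a 1.62-fold difference. The transgenic female read 0.34 and the array labelled wild-type female read 0.37, a 0.984-fold difference, so this gene did not separate the 2 females. Zfp90 on that array did not read as in the wild-type males, but with 1 female per genotype, label, sex and single animal are not separable here. Between the females, the 7 genes called in the males alone went both ways. Scd1, higher in the transgenic males, read -0.91 on that array and 1.15 in the transgenic female. Ifi27l2b, also higher in the transgenic males, read 1.09 and 0.72. Whether the label is right stays unsettled. Each value below that uses the array takes it as wild type. Group means were 0.46 ± 0.12 (SD, n = 3) and -0.05 ± 0.28 (SD, n = 4), with an exact permutation p of 0.0571 one-sided and 0.0857 two-sided, where 0.0286 is the smallest a one-sided test of 35 splits can give. Those splits exchange females with males, so the permutation p takes no account of sex. The adjusted p over all features was 0.678 in limma. Zfp90 was read by 1 probe, and neither its position in the transcript nor the structure of the transgene is given in the sources used here. The 15 genes beside Zfp90 on its chromosome (gene order of assembly GRCm38.p6), among them Smpd3 and Cdh3, had a median difference of -0.03, adjusted p = 0.525.

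Genes of fatty acid synthesis led the comparison of transgenic with wild-type liver. Scd1, the desaturase that makes monounsaturated fatty acids, averaged 1.46 ± 0.28 (SD, n = 3) in transgenic and -0.06 ± 0.56 (SD, n = 4) in wild-type animals, a 3.02-fold difference of 1.59 ± 0.14 SE. Acly, which supplies cytosolic acetyl-CoA, was at 1.25 ± 0.03 against -0.09 ± 0.24, 2.49-fold. Il33, a cytokine of the interleukin-1 family, was at 0.84 ± 0.34 against -0.08 ± 0.27, 1.83-fold. In these 3 genes each transgenic animal lay above all 4 animals labelled wild type, and each had an adjusted p of 0.0947 in limma, short of the threshold of 0.05. No feature passed: limma called 0 of 22218, with 1536 at an unadjusted p under 0.05 (848 higher, 688 lower) where chance gives 1111. Transgenic animals lay above all wild-type animals in 705 features (3.17%) and below all in 631 (2.84%), where chance gives 2.86% each way.

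The other genes with the smallest p likewise did not pass. Of those higher in transgenic animals, the fatty acid transporter Cd36 differed by 1.60 ± 0.22 SE, the secreted proteoglycan Prg4 by 1.05 ± 0.17, Pgap6 by 0.82 ± 0.12, the fatty acid elongase Elovl6 by 0.65 ± 0.10 and the drug-metabolizing Cyp2b10 by 0.62 ± 0.09, with adjusted p from 0.471 to 0.475. Cd36 overlapped between genotypes, since the array labelled wild-type female read 1.18 and transgenic male 1 read 0.49. Of those lower, 1700113H08Rik differed by -1.39 ± 0.19 SE, the kinase Plk3 by -0.83 ± 0.13, the mitochondrial nucleotide carrier Slc25a33 by -0.80 ± 0.11, the steroid dehydrogenase Hsd3b2 by -0.71 ± 0.13 and Hsdl2 by -0.58 ± 0.09. Genotypes also overlapped in 1700113H08Rik and Hsd3b2, where the array labelled wild-type female (-1.39 and -2.57) lay below both transgenic males. Armcx3 and Hadha, a subunit of the mitochondrial trifunctional protein of fatty acid oxidation, each differed by -0.47, and Moxd1 by -0.46, with adjusted p of 0.495 or less in this set of 8. The count of 0 became 7 when the males were fitted alone, 4 among the 50% of features with the largest ratios in size (Scd1, Acly, Cd36 and 1700113H08Rik), a set that a change from the pool itself helps to enter, and 2851 with array weights, whose estimation did not converge and gave wild-type male 2 a weight of 29.3 and no other array more than 2.42.

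**Figure D1:**
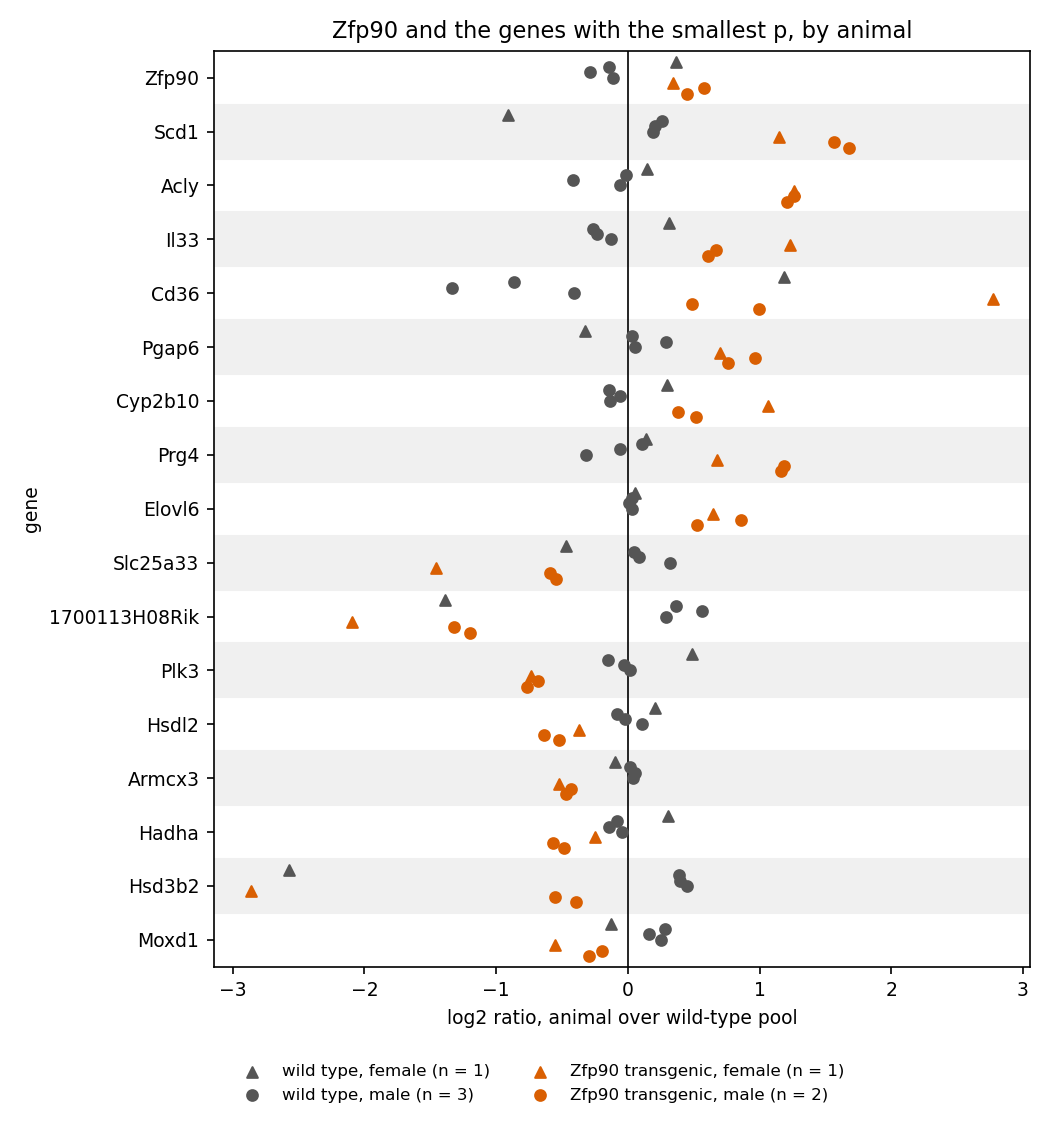
Log2 ratio of each animal to the wild-type pool (horizontal axis) for Zfp90 and the 8 genes with the smallest p in each direction (vertical axis), 1 point per animal, triangles for females and circles for males. For Scd1, transgenic animals lie between 1.15 and 1.68 and wild-type animals between -0.91 and 0.26, while the 2 females coincide for Zfp90.

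Among the 36 gene lists, lipid synthesis was higher and fatty acid oxidation lower in the transgenic animals. Of 24 measured genes for fatty acid and triglyceride synthesis, 20 had a positive and 4 a negative difference, with a median of 0.21 (1.16-fold; camera, adjusted p = 1.3e-05). That call was lost at adjusted p = 0.379 with an estimated correlation. Past the threshold were 0 members over all genes and 4 adjusted over the list alone, all higher: Scd1, Acly, Elovl6 and the acetyl-CoA synthetase Acss2 (0.86 ± 0.17 SE). Of 24 genes for fatty acid oxidation and ketogenesis, 19 were on the negative side, with a median of -0.17 (1.12-fold; adjusted p = 1.3e-05, and adjusted p = 0.178 with an estimated correlation). It held 0 members past the threshold over all genes and 5 adjusted over the list alone, all lower: Hadha, Hadhb (-0.87 ± 0.22 SE), the isomerases Eci1 and Eci2 (-0.40 ± 0.08 and -0.43 ± 0.13), and the carnitine carrier Slc25a20 (-0.47 ± 0.11). In both lists the call held with each of the 7 animals left out. The correlation was estimated at 0.073 for the synthesis list, above the preset 0.01, and at -0.021 for the oxidation list, below it. A higher correlation among its genes therefore does not account for the lost call of the oxidation list. PPAR alpha target genes had 15 of 19 members on the negative side and a median of -0.18 (adjusted p = 0.015, and adjusted p = 0.46 with an estimated correlation). Their single member past the threshold adjusted over the list alone, Cd36, was higher, with 0 over all genes. This call ended without transgenic male 2 (adjusted p = 0.328), without wild-type male 3 (0.164) or without either female (0.0597).

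Of the immune lists, those of macrophage, interferon-stimulated, acute phase and complement genes were higher in the model over all 7 animals, while lymphocyte and neutrophil markers did not pass. Between the 2 females the first 3 went the other way, with medians of -0.28, -0.36 and -0.14. Macrophage and Kupffer cell markers had a median of 0.22 (1.17-fold), with 21 of 26 genes positive (camera, adjusted p = 9.04e-05, and adjusted p = 0.46 with an estimated correlation). Past the threshold were 0 over all genes and 1 adjusted over the list alone, the scavenger receptor Cd163 (1.16 ± 0.19 SE, 2.23-fold). Marco, another scavenger receptor, read -0.02 and 0.10 in the transgenic males and -1.84 to -1.31 in the wild-type males, with 1.15 in the transgenic female and 1.29 on the array labelled wild-type female, and did not pass. Interferon-stimulated genes had a median of 0.17 with 27 of 32 positive (adjusted p = 0.00029, and adjusted p = 0.46 with an estimated correlation), 0 past over all genes and 1 adjusted over the list alone, the antiviral Mx1 (0.63 ± 0.12 SE). Acute phase genes had a median of 0.18 with 16 of 22 positive (adjusted p = 0.00354, and adjusted p = 0.46 with an estimated correlation). Of these 0 passed over all genes and 2 adjusted over the list alone, Steap4 (0.79 ± 0.14 SE) and the serum amyloid gene Saa2 (1.63 ± 0.34 SE, 3.10-fold). Complement and coagulation genes had a median of 0.09 with 21 of 27 positive (adjusted p = 0.0136, and adjusted p = 0.46 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Leaving out 1 animal ended the interferon call (adjusted p = 0.108 without wild-type male 3, 0.0868 without transgenic male 1), the acute phase call (0.119 without transgenic male 2) and the complement call (0.178 without transgenic male 1, 0.0694 without wild-type male 4, 0.0548 without wild-type male 3). In the first 3 of these lists the array labelled wild-type female lay with the transgenic animals, at a macrophage median of 0.52.

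Stress, bile acid and male-biased genes were lower as groups in the model over all 7 animals, though male-biased genes went the other way between the 2 females (median 0.47). Genes of ER stress and the unfolded protein response were on the negative side in 20 of 22 cases, with a median of -0.18 (adjusted p = 3.19e-05, and adjusted p = 0.46 with an estimated correlation). The secreted chaperone-like Creld2 read -1.52 to -1.11 in transgenic and -0.78 to 0.72 in wild-type animals, and the ER chaperone Hspa5 differed by -0.36 ± 0.12 SE. Neither passed, and the list held 0 past over all genes and 0 adjusted over the list alone. Heat shock and immediate early genes had a median of -0.15 with 17 of 23 negative (adjusted p = 0.0021, and adjusted p = 0.379 with an estimated correlation), and 0 passed either way, Hsp90aa1 (-0.47 ± 0.12 SE) included. Bile acid synthesis and transport genes had a median of -0.19 with 14 of 21 negative (adjusted p = 0.00784, and adjusted p = 0.46 with an estimated correlation). It held 0 past over all genes and 1 adjusted over the list alone, the nuclear receptor Nr0b2 (-0.57 ± 0.11 SE), a repressor of bile acid synthesis. Male-biased liver genes had a median of -0.33 with 15 of 19 negative (adjusted p = 0.0021, and adjusted p = 0.46 with an estimated correlation), with 0 past over all genes and Moxd1 alone adjusted over the list alone. Oxidative phosphorylation genes were slightly higher, with a median of 0.11, 26 of 35 positive and 0 past either way (adjusted p = 0.00551, and adjusted p = 0.46 with an estimated correlation). Calls ended for heat shock and oxidative phosphorylation without either female (adjusted p = 0.203 and 0.475), for bile acids without transgenic male 1 (0.132), and for male-biased genes without transgenic male 1 (0.0973) or 2 (0.0688). The mean of the male-biased genes, -0.34 over all animals, was -0.20 without transgenic male 1 and -0.65 without either female. Cyp7b1 and Slco1a1 are in both the bile acid and the male-biased list.

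**Figure D2:**
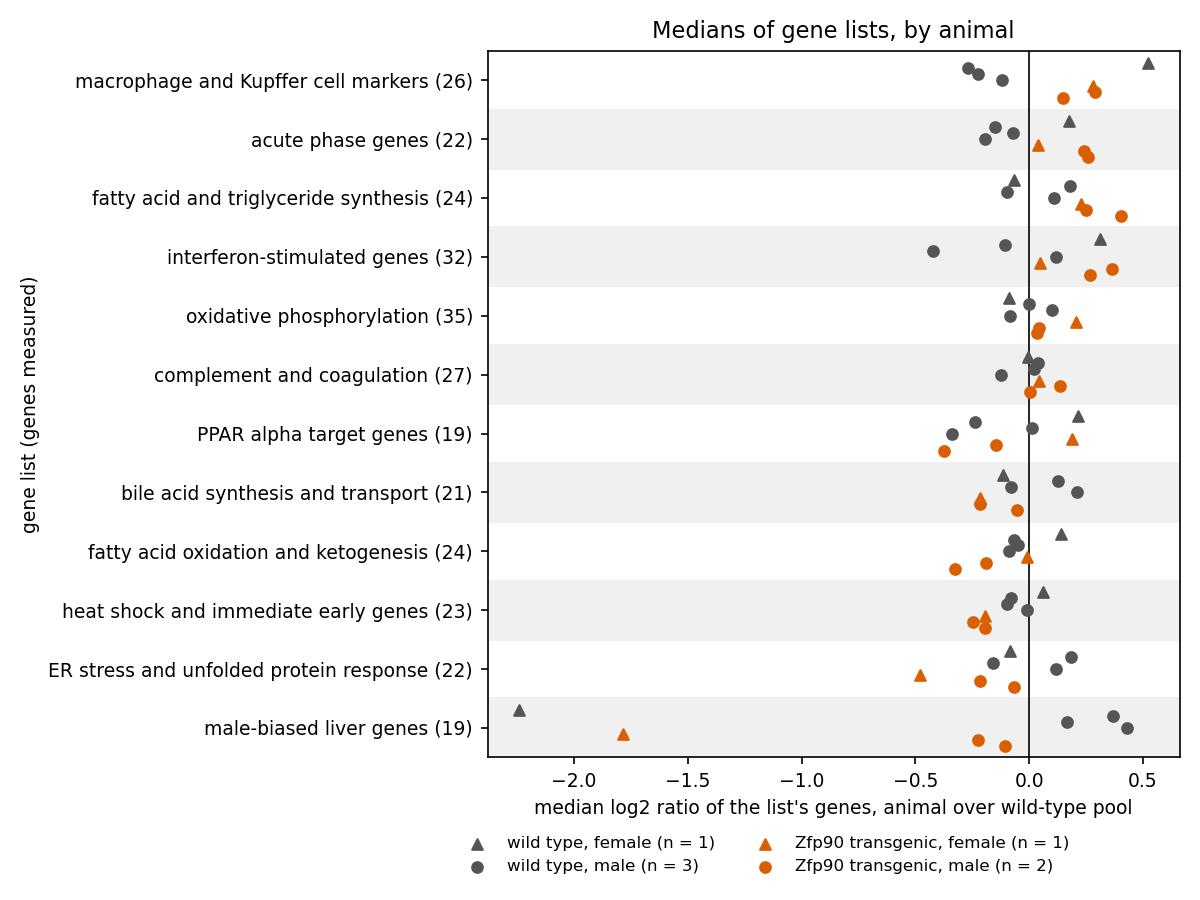
Median log2 ratio to the wild-type pool over the genes of each list (horizontal axis), 1 point per animal, for the 12 lists past camera's threshold (vertical axis, with the number of genes measured). In the list of fatty acid and triglyceride synthesis, transgenic animals lie between 0.23 and 0.40 and wild-type animals between -0.10 and 0.18.

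The remaining 24 lists did not pass, and none of the 36 held a member past the threshold over all genes. Female-biased liver genes came nearest of the sex lists (median 0.38, adjusted p = 0.069), with 4 members adjusted over the list alone: Cyp2b9 (1.71 ± 0.36 SE), Cyp2b13 (1.62 ± 0.43) and Hao2 (1.56 ± 0.40) higher, and Cyp2c40 (-0.39 ± 0.10) lower. Adjusted over the list alone, Cps1, the entry enzyme of the urea cycle, was higher in the lists of amino acid catabolism and of hepatocyte markers (0.59 ± 0.11 SE), and Cyp2e1 was lower in those of drug metabolism and of hepatocyte markers (-0.49 ± 0.11). In the same way Cyp2b10 was higher in drug metabolism and the haem oxygenase Hmox1 (0.93 ± 0.20) in the NRF2 and glutathione list. For these lists adjusted p was 0.187 (amino acid catabolism), 0.729 (hepatocyte), 0.374 (drug metabolism) and 0.104 (NRF2). With 0 members adjusted over the list alone, the other metabolic lists had adjusted p of 0.187 (TCA cycle), 0.145 (cholesterol synthesis), 0.997 (lipoproteins), 0.234 (glucose and glycogen) and 0.075 (insulin and growth hormone signalling). So did the lists of the clock (0.208), cell cycle (0.172), ribosomal proteins (0.729), proteasome (0.763) and sex chromosomes (0.763). Markers of other cell types also had 0 such members: lymphocytes (0.226), neutrophils (0.997), stellate cells (0.998), endothelium (0.645), bile duct (0.394), red blood cells (0.289), adipocytes (0.289) and exocrine pancreas (0.157).

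Fitted in the 5 males alone, 7 genes passed limma's threshold, all named here after their values were seen and each at an adjusted p of 0.026. Transgenic males were higher in Slc2a4, an insulin-responsive glucose transporter, by 2.94 ± 0.21 SE, in Cyp2b13 by 2.33 ± 0.17, in Cyp2b9 by 2.29 ± 0.18, in the interferon-induced Ifi27l2b by 2.23 ± 0.14 and in Scd1 by 1.40 ± 0.10. They were lower in 1700113H08Rik (-1.67 ± 0.12) and in Cyp7b1 (-1.38 ± 0.11), a male-biased oxysterol hydroxylase. Cyp2b9 and Cyp2b13 are female-biased enzymes, at 0.11 and -0.41 (Cyp2b9) in the transgenic males against -2.52 to -2.27 in the wild-type males. In the males, 18 of 19 male-biased liver genes lay lower in transgenic animals (median -0.50; camera, adjusted p = 3.1e-11, and adjusted p = 0.17 with an estimated correlation). Past the threshold were 1 member over all genes and 9 adjusted over the list alone. The correlation estimated for this list was -0.0068, below the preset 0.01, and fry called the list too (adjusted p = 0.0455). Of 21 female-biased genes 14 lay higher (median 0.16, adjusted p = 0.00225, and adjusted p = 0.391 with an estimated correlation), 2 over all genes and 4 adjusted over the list alone. Macrophage markers had a median of 0.50 in the males (adjusted p = 3.84e-13, and adjusted p = 0.391 with an estimated correlation), with 0 past over all genes and 13 adjusted over the list alone. This fit rests on 2 transgenic and 3 wild-type males.

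**Figure D3:**
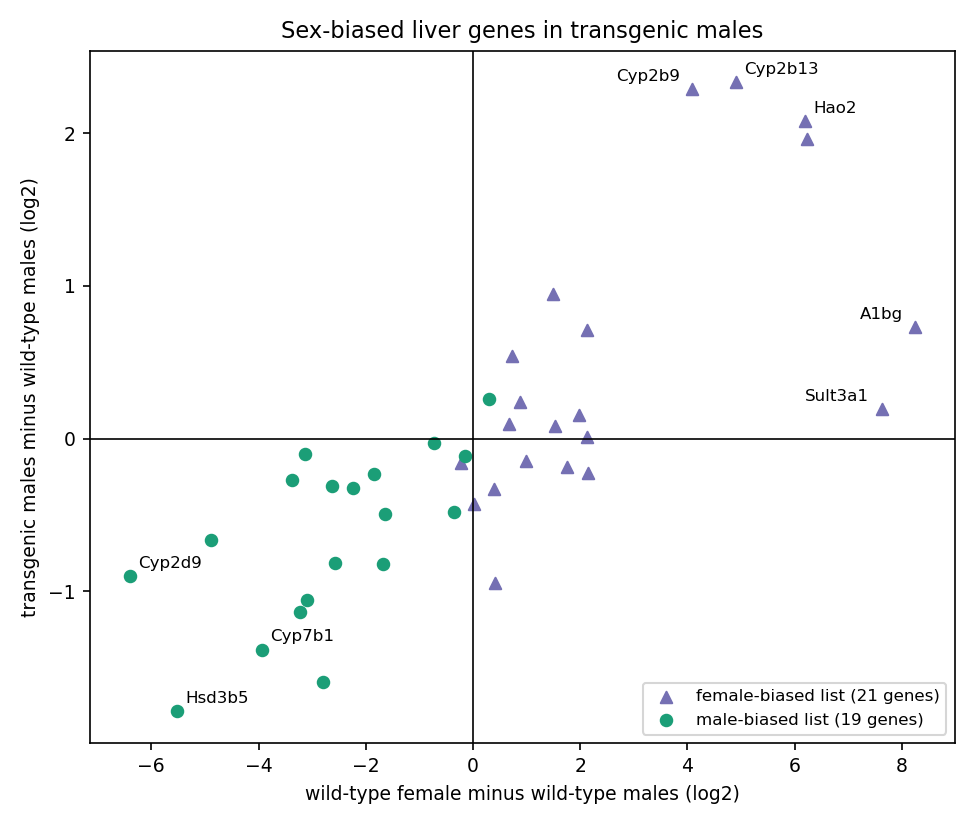
Difference of the transgenic males from the wild-type males (log2, vertical axis) against the difference of the array labelled wild-type female from the wild-type males (log2, horizontal axis) for 21 female-biased and 19 male-biased liver genes, 1 point per gene. Both axes use the same 3 wild-type males, and the female-biased Cyp2b9 and Cyp2b13 lie at 2.29 and 2.33 on the vertical axis while Sult3a1 lies at 0.19.

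Females and males differed in 78 features in limma (37 higher and 41 lower in females, 67 of them named genes). The 5 largest fitted differences among those higher in females began with A1bg and Sult3a1, whose male ratios came near the lower limit of the values, so these 2 folds are approximate. A1bg averaged 1.98 in 2 females and -6.02 in 5 males (247-fold, difference 7.95 ± 0.43 SE, adjusted p = 0.000389), the sulfotransferase Sult3a1 was 210-fold higher (adjusted p = 0.00041), C730007P19Rik 118-fold (8.22e-06), the hydroxyacid oxidase Hao2 40.8-fold (0.00296) and Slc22a26 34.3-fold (0.0163). Lower in females were Cyp2d9 (54.1-fold, adjusted p = 0.000402), Serpina4-ps1 (34.9-fold, 0.00944), the steroid dehydrogenase Hsd3b5 (difference -4.39 ± 0.51 SE, 0.0187), Susd4 (20.4-fold, 0.000555) and Nat8 (18.2-fold, 0.000305). The Y-linked Kdm5d was 9.96-fold lower in females (adjusted p = 0.000645), whereas Uty, at -0.18 and -0.06 in females and -0.02 to 0.15 in males, did not pass (0.721). Female-biased liver genes had a median difference of 1.63, with 20 of 21 positive, 8 past over all genes and 18 adjusted over the list alone (camera, adjusted p = 2.8e-26, and adjusted p = 0.0307 with an estimated correlation). Male-biased genes had a median of -2.20, with 18 of 19 negative, 9 past over all genes and 17 adjusted over the list alone (adjusted p = 2.02e-27, and adjusted p = 0.152 with an estimated correlation).

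In females, macrophage markers were also higher (median 0.41, 25 of 26 positive, adjusted p = 3.05e-08, and adjusted p = 0.469 with an estimated correlation), as were PPAR alpha targets (0.22, adjusted p = 4.63e-07) and fatty acid oxidation genes (0.24, adjusted p = 1.59e-05). The last 2 calls were lost with an estimated correlation (adjusted p = 0.247 and adjusted p = 0.113 with an estimated correlation). Markers of lymphocytes (0.17, adjusted p = 0.000387), stellate cells (0.18, 0.00516) and endothelium (0.20, 0.00609) were higher in females too. They were lost at adjusted p = 0.469, 0.246 and 0.469 with an estimated correlation. Lower in females, beside male-biased genes, were the lists of sex-chromosome genes (-1.74, adjusted p = 0.000834), ER stress (-0.20, 0.00514), bile acids (-0.08, 0.00609) and the proteasome (-0.11, 0.00737). These were lost at adjusted p = 0.256, 0.516, 0.469 and 0.469 with an estimated correlation. The bile acid list shares Cyp7b1 and Slco1a1 with the male-biased list, so the calls of these 2 lists overlap. Its mean difference was -0.27, beside the median of -0.08. The sex-chromosome list held 2 measured genes, Kdm5d and Uty. As Kdm5d settled the direction of the ratios, the direction of that list's call was fixed in advance. Camera called 12 lists in all, of which the female-biased list held with an estimated correlation. Fry called 5 of them: female-biased (adjusted p = 0.00221), male-biased (0.0111), sex-chromosome (0.0111), fatty acid oxidation (0.0167) and stellate cell genes (0.0499). The count of 78 became 36 without the array labelled wild-type female, 39 without wild-type male 2, 48 without wild-type male 4, 45 without transgenic male 2 and 254 without the transgenic female. Slc22a26, Serpina4-ps1 and Hsd3b5 were no longer called without the array labelled wild-type female (adjusted p = 0.107, 0.107 and 0.07). Slc22a26 was also not called without wild-type male 2 (0.0519) or transgenic male 2 (0.0598), nor Hsd3b5 without wild-type male 2 (0.0566), wild-type male 4 (0.0552) or transgenic male 1 (0.066).

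The interaction of genotype and sex passed the threshold in 16 features, 10 of them named genes. The female difference sets 1 animal against 1, with the spread taken from the males, so a difference between sexes and one between single animals are not separable here. In 10 of the 16, the array labelled wild-type female was past 1.5 in size and the other 6 arrays within 1. In Tmem174, Rtn4r and Tex29, the array labelled wild-type female read 6.64, the upper limit of the values, while the other 6 arrays stayed within 0.25, 0.29 and 0.43 of 0. As that value is a limit, their interactions (female minus male transgene difference) are bounds on the deposited scale, at -6.21 or lower (adjusted p = 0.000639), -6.82 or lower (0.00271) and -6.95 or lower (0.00523). Spsb1 read -2.03 on the array labelled wild-type female and 1.07 in the transgenic female (interaction 3.66 ± 0.24 SE, adjusted p = 0.00866). The keratin Krt23 read -0.20 and 1.60 in those females and -0.89 and -1.26 in the transgenic males (interaction 2.93 ± 0.25 SE, adjusted p = 0.0368). After quantile normalization, 4 of these 5 genes were no longer called: Rtn4r (-3.35, adjusted p = 0.132), Tex29 (-3.30, 0.204), Spsb1 (2.92, 0.0936) and Krt23 (2.70, 0.0635). Tmem174 stayed called, at -2.70 in place of -6.21. Spsb1 was also not called without wild-type male 2 (0.0721), nor Krt23 without wild-type male 2 (0.215), wild-type male 3 (0.0516) or transgenic male 2 (0.0789), or with array weights (0.0646). Of the lists, 5 passed, 0 of them with an estimated correlation, where the lowest adjusted p was 0.249. Macrophage markers differed by a median of -0.28 in females and 0.50 in males, interferon-stimulated genes by -0.36 and 0.48, acute phase genes by -0.14 and 0.34, male-biased genes by 0.47 and -0.50, and oxidative phosphorylation genes by 0.27 and 0.02. Across the 22218 features, which are not independent replicates, the female and male differences correlated at r = 0.069 (rho = 0.0891). The count of 16 became 4 without wild-type male 2 and 77 without wild-type male 4, and neither female can be left out.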

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

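The tests of the sex-biased, array and immune patterns below were chosen after the result was seen, while the counts of other splits were planned. Chance was not excluded by the 35 splits of the 7 animals into 3 and 4, for the 2 counts that could have done so. These splits did not all keep a female in each group, though sex stayed a term in the model. For features past the threshold, all 35 reach the real 0 by construction, so that count says nothing about chance (highest other 6). At an unadjusted p under 0.05, 9 of 35 splits gave at least the real 1536 features, and 5 of 35 gave at least the real 12 gene lists, with 15 as the highest other. The split of wild-type male 3, the transgenic female and transgenic male 1 from the rest gave 5279 features, several times the real count, with 0 past the threshold. Such a count may reflect a structure of the samples, which no test set apart from a chance maximum among the splits.

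Sex-biased liver genes of the transgenic males lay toward the female level. Of 28 list genes that differed over 2-fold between the array labelled wild-type female and the wild-type males, 26 did so, and the highest count in the other 9 splits of the 5 males was 22, where 10 splits are too few for a share under 0.1. Female RNA carried into these samples is argued against by 7 features almost off in wild-type males: they allow a median of 0.317% female RNA (-0.22% to 5.0%, the highest in Hao2 and Slc22a26), where the 15 male-biased genes among the 28 need a median of 45.5% ± 21.5 (SD). Cyp2b13 and Cyp2b9, called in the males and not among these 7 features, need 14.1% and 24.6%. Lower contrast of the transgenic male arrays cannot bring a ratio below 0, and 10 of the 15 male-biased genes lay below 0. The median of the 15, -0.38 ± 0.48 (SD), is within its spread of 0, so for the set lower contrast stays open. The SD over all probes was 0.254 and 0.259 on these arrays, within the 0.217 to 0.274 of the wild-type males. No loss of contrast shows in that measure. A difference by genotype stays open as well, and it rests on 2 transgenic males and on list calls that end with an estimated correlation. In the males, fry called the male-biased list (adjusted p = 0.0455) and not the female-biased list (0.133).

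The array labelled wild-type female held the extreme value in most of the 16 features past the threshold for the interaction of genotype and sex: in 10 its value was past 1.5 in size while the other 6 arrays stayed within 1. In 4 of these it was high, among them Tmem174 (interaction -6.21 or lower), Rtn4r (-6.82 or lower) and Tex29 (-6.95 or lower), read at the limit of the values, and a true level is argued against if that animal was 1 of the 4 in the pool, which the labels do not state: its log2 ratio then cannot exceed 2, and the lowest of the 4 was 2.63. In the other 6 it was low, and there a true low level has what it needs, again if that animal was in the pool. A pool short of that animal's share would put the wild-type males at 0.37, and their median was 0.365. The wild-type males also enter the interaction that picked these features. Against the same pool, the transgenic means of these 6 features ran from -0.64 to 0.56. Of these 6, 2 unnamed features did not follow, with wild-type males at -0.01 and 0.13. Spots with a faulty reading on that array are a candidate explanation for the high values, and the intensities that could show it were not used here.

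Macrophage, interferon and acute phase lists were higher in transgenic than wild-type males, while the transgenic female lay below the array labelled wild-type female, with interactions of -0.828, -0.817 and -0.573 (means over genes); these calls end with an estimated correlation (males alone, adjusted p = 0.391, 0.452 and 0.359; interaction, 0.249 as the lowest of any list). A lower share of hepatocytes would raise the markers of all other cell types alike, but the macrophage median exceeded that of endothelial, stellate and bile duct genes by 0.502 (permutation p = 1e-04 over genes, the smallest that 10000 resamples can give). That p takes genes as independent, while the correlation in the macrophage list was estimated at 0.277 in the males. It does not measure the spread between animals. The macrophage list shared 0 of its 26 genes with another list. The macrophage median was highest on the array labelled wild-type female (0.52), and the transgenic female (0.28) lay beside the transgenic males (0.29 and 0.15). An immune state of that 1 animal may account for the interaction and was not tested, and with 1 female per genotype animal and sex are not separable.

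Between 1 female per genotype, Spsb1 differed by 3.10 and Krt23 by 1.81, against -0.56 and -1.12 in males (interactions 3.66 and 2.93). For the same animals the interaction was 1.05 in male-biased liver genes and 0.301 in oxidative phosphorylation genes (means over genes), and both calls end with an estimated correlation (adjusted p = 0.249 and 0.558). Among 53 genes and list medians tested over the 4 wild-type arrays, 7 had 1 animal standing apart from the other 3, where chance gives about 1 in 20. In 6 of them it was the array labelled wild-type female, with gaps, as a share of the whole range, of 0.944 for Scd1, 0.861 for 1700113H08Rik, 0.979 for Hsd3b2, 0.901 for male-biased genes, 0.996 for female-biased genes and 0.858 for sex-chromosome genes. That array is the sole female of the 4, so sex sets it apart in Hsd3b2 and the 3 sex lists, and the comparison with chance says nothing there. Scd1 and 1700113H08Rik were also lower in females in limma's model (-0.82 and -1.34) without passing (adjusted p = 0.104 and 0.0608). Sex thus stays open for these 2 genes. The exocrine pancreas list set wild-type male 3 apart (0.855).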

How the results depend on the processing

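Males alone (planned, as were all alternatives but 1) gave 7 features in transgenic against wild type where the main model gave 0, and the 50% of features with the largest ratios in size gave 4, with 854 at an unadjusted p under 0.05 in place of 1536. A change from the pool itself helps a feature into that set. Array weights, whose estimation did not converge, gave 2851 and 7238, and put Zfp90 past the threshold (0.65, adjusted p = 0.0107, where the lowest of the other alternatives gave 0.206), with weight 29.3 on 1 wild-type male. They also turned the mean of PPAR alpha target genes from -0.18 to 0.019. Without 1 animal, these counts ran from 0 to 7 and from 804 to 3538. The 12 gene lists became 0 with an estimated correlation and 0 with fry (9 to 15 without 1 animal). Female against male gave 49 features after quantile normalization and 162 in the 50% set, in place of 78 (36 to 254 without 1 animal). The transgene effect by sex gave, in place of 16, 6 after quantile normalization, 9 with array weights, 7 with named genes alone, 57 in the 50% set, and 9 without 14 features above the pool's bound or at the limit, which was chosen after seeing the data (4 to 77 without 1 animal). The cause was not tested. Median centring and quantile normalization kept all 12 list calls and the signs of the called lists. Of 256 alternative values of the 16 other named genes in transgenic against wild type, 0 changed sign and 26 passed the threshold: 16 with array weights, 4 in the 50% set, and 2 (Scd1 and 1700113H08Rik) in each of males alone and without either female, which are 1 and the same fit. The rule on missing values had nothing to act on, and turning the sign was not needed, so neither was run. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Signal over background could not be weighed from ratios.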
